A study of Homo sapiens with 6 samples.

How the data were processed

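Nascent small RNA 3′ ends were sequenced in 6 libraries from human HEK 293T-REx TOE1-degron cells, 3 labelled TOE1-present and 3 labelled TOE1-depleted. Per the labels' protocols, TOE1 was depleted with 600 µM of the auxin indole-3-acetic acid for 8 hours, and nascent RNA was marked with 0.2 mM ethynyl uridine for 8 hours. RNA of 100 to 500 nt was cut from a denaturing gel, depleted of ribosomal RNA, freed of end phosphates, and ligated at the 3′ end to an adaptor before the marked RNA was captured and made into cDNA. Per the labels, the adaptor was AG10 in the 3 TOE1-present libraries and in TOE1-depleted replicate 1, and AG11 in TOE1-depleted replicates 2 and 3. Adaptor and condition were therefore partly confounded, and a difference in ligation or read-out between the adaptors enters 2 of the 3 TOE1-depleted libraries. The submitters' processing notes name STAR 2.7.8a and the genome build hg38; the annotation, the treatment of reads that map to several gene copies and the use of molecular identifiers are not given in the sources used here.

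The only file analysed was the authors' deposited table of 142 RNAs, with the comparison of TOE1-depleted against TOE1-present libraries already made. Per the file headers it holds raw read counts per RNA for each of the 6 libraries, which the authors deposited without normalization. Per the file headers it also holds, for each RNA, the 3′ end position in control cells within a window from −10 to 50 nt around position 0, the differences named TE and GE, and the number of untemplated bases. Shares of reads by tail type stand beside them, each with the difference between conditions and a p-value from the authors. The headers do not spell out TE and GE. In 142 of 142 rows TE minus GE equalled the summed changes of A, U, C and G tail bases to within 1e-06 nt, so TE was read as the total end with its tail and GE as the end of the genome-templated part. Position 0 was read as the annotated 3′ end in the annotation the authors used, and positive positions lie downstream. The deposited p-values of these measures had the form of a 2-sided test on library means with a pooled variance: 143 of those of the tail measures equalled 0.373901 to within 1e-06, the value such a test gives when a single library differs from 0. A second kind of deposited p-value, from a Kolmogorov-Smirnov test on pooled reads, treats reads as replicates and was used only as an alternative. Per-library end positions and tails were not analysed here, because the deposited table gives these measures per condition only.

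The deposited counts summed to 34581 to 57078 reads in the TOE1-present libraries and to 32813 to 75353 reads in the TOE1-depleted libraries, and row totals ran from 20 to 58467 with a median of 170.5. Many rows therefore rest on few reads, and the error of each difference was used to weigh it. That error was recovered from the deposited difference and p-value, with degrees of freedom set by the number of libraries that had reads for the RNA, and gives the 95% intervals printed. Intervals cover the spread between libraries only. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The 142 rows carried 190 gene identifiers, of which 189 were found in GENCODE 44, and 12 rows merged several genes. Coordinates are 1-based on hg38 from GENCODE 44.

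RNAs were assigned to classes by gene symbol with lists fixed before the data were examined, and so were the class tests, the rule for named RNAs and all alternatives except those named at the end as added. The Sm class holds the U1, U2, U4, U5, U11, U12, U4atac and U7 snRNAs; no row of U7 was present. Further lists were U6 and U6atac, genes of snRNA families named as pseudogenes, the independently transcribed snoRNAs U3, U8 and U13, other C/D snoRNAs, H/ACA snoRNAs, scaRNAs and the RNA polymerase III RNAs 7SK, 7SL, Y, RNase P, RNase MRP and vault RNA. Lists for telomerase RNA, rRNA, tRNA and histone mRNA matched no row by symbol. Named were the RNAs of the Sm, U6 and U3/U8/U13 lists with at least 100 reads, up to 10 RNAs in each direction outside these lists past the threshold with at least 100 reads, and the controls RN7SK, RN7SL1, RN7SL2, RMRP, RPPH1, TERC, RNY1 and RNY3 where measured, 23 RNAs in all. Per-RNA calls used the deposited p-values of the 139 RNAs that had them, adjusted by Benjamini-Hochberg, with a threshold of 0.05. The share of called RNAs in the Sm class was set against all other RNAs with Fisher's exact test. Class medians were placed among 10000 random lists matched on read number in 5 strata, and the Sm class was compared with 6 other classes by 2-sided permutation of the difference of medians, exact wherever a group had under 10 RNAs and otherwise with 100000 resamples.

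The plan for per-library end positions could not be followed, because those values were not in the table; abundance was tested instead on the counts as an addition. edgeR 4.0.16 quasi-likelihood tests were fitted in R 4.3.3 to the counts of 101 RNAs kept by its expression filter, with TMM normalization and no covariate. DESeq2 1.42.0 and limma 3.58.1 served for alternatives, and class statistics were computed in Python 3.11.15 with scipy 1.17.1. The labels give both groups replicate numbers 1 to 3 without saying what they share. On log2 CPM with a prior count of 2, deviations of same-numbered libraries from their group means correlated at 0.907, 0.258 and 0.807 over the 101 RNAs, all above the bound of 0.1 set for pairing, although a library was closest to its own number in 1 of 3 cases only, so the numbers were treated as pairs and a fit with the replicate number as a block was made. In 4 rows of the RMRP, 7SK and U2 families the spread of reads over gene models differed in both replicate 1 libraries. The 7SK row, AL162581.1, was not among the 101 RNAs. Without the RMRP and U2 rows, over 98 RNAs, the correlations were 0.0197, 0.00892 and 0.144, with the same tally. The pairing thus rests on those rows. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom was 14.5 at the lowest.

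The steps were tested on simulated data. With counts drawn from the means and the per-RNA dispersions of the 101 RNAs tested, 20 of them changed, the edgeR step recovered 1.5% of 1.5-fold, 33.5% of 2-fold and 76.75% of 3-fold changes, and 25.0%, 10.7% and 3.16% of its calls were false. A first simulation with 1 dispersion for all RNAs (0.240) recovered 0%, 3.25% and 26.0%. After that result was seen, dispersions fitted without the 4 rows (median 0.0296) were tried, which gave 18.5%, 64.5% and 89.5% of the changes in 99 RNAs, with 10.8%, 4.09% and 3.76% of the calls false; these describe the fit without those rows, not the main test. For the moderated test of end positions on 139 RNAs, 88% of changes of 4 standard deviations were recovered and 7.37% of the calls were false. The class-median step recovered 92.5% of shifts of 1.5 standard deviations in 11 of 140 RNAs. It was scored at an unadjusted p under 0.05, with noise unrelated to read number. The class medians of the data were adjusted over 40 class values, so this is not the power of the test used. Alternatives covered the threshold, the adjustment, minimum reads and size of change, class definitions, normalization, low-count filter, replicate block, adaptor and leaving out each library. Added after seeing the data were limma's moderated test of the deposited differences, the deposited Kolmogorov-Smirnov p, the DESeq2 Wald test, library totals without TMM, the fits without the 4 rows or with their gene models summed, and the adaptor as a covariate.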

Results

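Libraries of nascent small RNA 3′ ends, 6 in all, were compared, 3 from cells with TOE1 and 3 from cells depleted of it. TOE1 is a 3′ exonuclease that trims small nuclear RNAs, and the series asks which small RNAs it processes in cells. The line is a HEK 293T-REx derivative, from human embryonic kidney, in which TOE1 carries a degron and is degraded when auxin is added. The table listed 142 small RNAs: 12 Sm-class snRNAs, 2 U6-type snRNAs, 3 genes named as snRNA pseudogenes, 3 independently transcribed snoRNAs, 19 other C/D snoRNAs, 67 H/ACA snoRNAs, 16 scaRNAs, 14 RNA polymerase III RNAs and 6 RNAs outside these lists. The TOE1-present libraries held 57078, 34581 and 38515 reads, and the TOE1-depleted libraries 75353, 32813 and 58153 reads. The 5 most abundant RNAs took 61.6% to 74.96% of the reads of a library. The table held small RNAs only, so the loss of TOE1 itself was not checked here.

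Reads of 3 RNA families were spread over gene models in another way in replicate 1 of both groups than in the other libraries. For RMRP, the RNA of RNase MRP, the model ENSG00000269900 had 0 reads in replicate 1 of each group and 1985 to 5460 reads in the other libraries, while the model ENSG00000277027 had 2645 and 4200 reads in replicate 1 and 160 to 352 elsewhere. The RMRP model ENSG00000269900 was the identifier not found in GENCODE 44. The 7SK model AL162581.1 at chromosome 6, 52995620 to 52995950, had 3533 and 6348 reads in the replicate 1 libraries and 0 in the other 4. RN7SK had 195 to 271 reads in each library. Its model, at 52995621 to 52995948 on the same strand, lies within AL162581.1. The U2 model AC024051.4 at chromosome 17, 43290291 to 43290481, had 5602 reads in TOE1-present replicate 1, 261 in replicate 2, 15817 in TOE1-depleted replicate 1 and 0 in the other 3. The authors' deposited table gives no p for the end positions of AL162581.1 and AC024051.4, and these entered no end comparison.

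**Figure D1:**
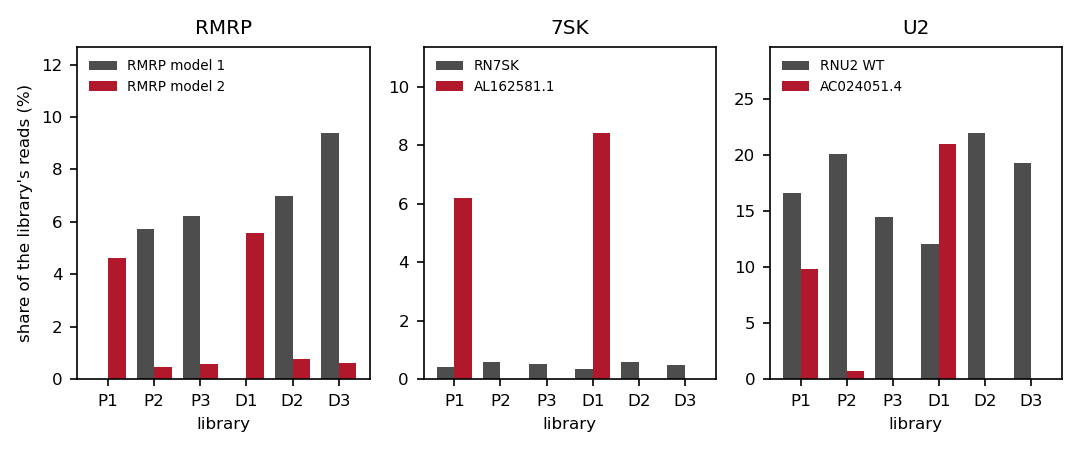
Share of each library's reads (%, y axis) on 2 gene models of RMRP, 7SK and U2, for TOE1-present replicates (P1 to P3) and TOE1-depleted replicates (D1 to D3), 1 bar per model and library. RMRP model 1 is ENSG00000269900 and model 2 is ENSG00000277027. AL162581.1 held 6.19% and 8.42% of reads in P1 and D1 and had 0 reads in the other 4 libraries.

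The first comparison asked at which RNAs the 3′ end moved when TOE1 was depleted. The ends of U1, U2 and RNU2-2P, all RNAs of the spliceosomal snRNA families, moved downstream, and none of the other 136 RNAs with a p passed the adjusted threshold in either direction. Adjusted p were computed from the deposited p, and the 95% intervals were recovered from the deposited difference and p. The genome-templated end of U2 (row RNU2 WT, 49497 reads, merged from 12 genes) lay 2.26 nt further downstream in TOE1-depleted than in TOE1-present cells in the authors' deposited table (95% interval 1.97 to 2.56 nt, adjusted p = 0.00403). That of U1 (row RNU1 WT, 9645 reads, merged from 10 identifiers) lay 0.888 nt further downstream in the authors' deposited table (0.695 to 1.08 nt, adjusted p = 0.009999). The largest of the 3 changes was that of RNU2-2P (ENSG00000222328, 5603 reads), a U2 gene whose symbol marks it as a pseudogene, at 7.47 nt in the authors' deposited table (6.03 to 8.92 nt, adjusted p = 0.00953).

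With the untemplated tail counted, the total end moved by 2.28 nt for U2, 7.56 nt for RNU2-2P and 1.352 nt for U1 in the authors' deposited table, with adjusted p of 0.0101, 0.0101 and 0.0321. For U1 the A bases in the tail made up 0.328 nt of the difference in the authors' deposited table, whose unadjusted p for them was 0.0491. In TOE1-present cells the mean end position was −0.283 nt for U2, 0.801 nt for RNU2-2P and 1.601 nt for U1 in the authors' deposited table. On hg38, the U1 gene RNU1-1 lies on chromosome 1, 16514122 to 16514285, minus strand, a 164 nt snRNA gene that ends in CGCTTTCCCCTG, and the genome continues with ACTTTCTGGAGT. The U2 gene RNU2-1 lies on chromosome 17, 43233787 to 43233977, minus strand, with 191 nt ending in GGTGCACCCCCT and followed by CCGGGGATACAA. RNU2-2P lies on chromosome 11, 62841619 to 62841809, minus strand, with 191 nt ending in GGTGCACTCTCC and followed by CTTCGGGGAGAG. At an unadjusted p under 0.05, 18 RNAs were counted for the genome-templated end and 11 for the total end in the authors' deposited table. The U1 and U2 rows merge near-identical copies whose reads cannot be parted, and the U2 row leaves out the reads on AC024051.4. End positions were not available per library, so no fit with AG10-ligated libraries alone could be made for them.

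**Figure D2:**
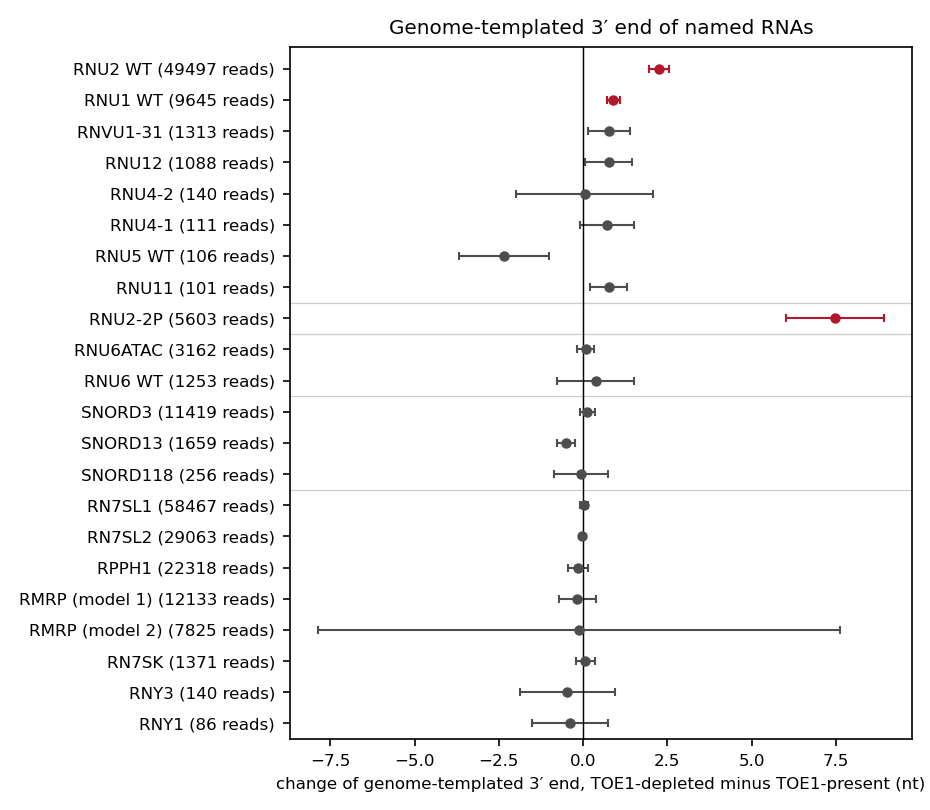
Change of the genome-templated 3′ end, TOE1-depleted minus TOE1-present (nt, x axis), for the 22 named RNAs with a p in the authors' deposited table, with total reads beside each name. Points are the deposited differences and bars the 95% intervals recovered from the deposited p; red marks adjusted p under 0.05. RNU2-2P stands at 7.47 nt, RNU2 WT at 2.26 nt and RNU1 WT at 0.888 nt.

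None of the other Sm-class RNAs passed, and their changes went both ways. At an unadjusted p under 0.05 in the authors' deposited table, the class held 5 downstream and 1 upstream genome-templated ends of 11, U1 and U2 included. For the total end it held 2 and 0. Of the 11 genome-templated values, 9 were above 0. The genome-templated end differed by 0.756 nt for U11, by 0.758 nt for U12, both of the minor spliceosome, and by 0.780 nt for the U1 variant RNVU1-31 in the authors' deposited table, with adjusted p of 0.282, 0.358 and 0.284. The values were 0.700 nt for RNU4-1 and 0.0404 nt for RNU4-2 in the authors' deposited table, neither past the threshold. U4atac, RNVU1-27 and RNVU1-19, with 27, 25 and 20 reads, stood at 0.996, 0.407 and −1.44 nt in the authors' deposited table, each with an interval that included 0. For U5 the genome-templated end lay at −2.35 nt (95% interval −3.69 to −1.01 nt, adjusted p = 0.189) and its total end at 0.681 nt relative to TOE1-present cells in the authors' deposited table, on 106 reads. The U5 row was merged from 5 genes, whose reads cannot be parted. For the genome-templated end, 2 of 11 Sm-class RNAs passed the threshold over all RNAs tested. Adjusted over the list alone, 3 passed, U1 and U2 downstream and U5 (adjusted p = 0.0299) upstream. For the total end the list alone gave 2, U1 and U2. U6 and U6atac, transcribed by RNA polymerase III and bound by the Lsm ring, differed by 0.369 and 0.0703 nt in the authors' deposited table, with adjusted p of 0.794 and 0.833. The total end of U6 stood at −0.593 nt in the authors' deposited table (adjusted p = 0.354), 1 call of 2 when adjusted over the list alone.

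Among the capped snoRNAs, U3 (row SNORD3) differed by 0.123 nt and U8 (SNORD118) by −0.0578 nt, while U13 (SNORD13) differed by −0.521 nt with an adjusted p of 0.162 in the authors' deposited table. Over all RNAs 0 of these 3 passed and 1, U13, had an unadjusted p under 0.05; adjusted over the list alone, U13 passed, upstream. The control RNAs lay close to 0 in the authors' deposited table: 0.0229 nt for RN7SL1 (95% interval −0.0831 to 0.129 nt), −0.0214 nt for RN7SL2 (−0.0640 to 0.0211 nt), −0.143 nt for RPPH1 (−0.437 to 0.151 nt) and 0.0651 nt for RN7SK (−0.206 to 0.336 nt). The models of RMRP differed by −0.168 nt (−0.715 to 0.378 nt) and, far less precisely, by −0.128 nt (−7.87 to 7.61 nt) in the authors' deposited table. RNY1 and RNY3, with 86 and 140 reads, differed by −0.393 and −0.471 nt in the authors' deposited table, within their errors. In the C/D, H/ACA, scaRNA and RNA polymerase III lists 0 RNAs passed, over all RNAs or adjusted over the list alone, by the deposited p or by limma's moderated test. At an unadjusted p under 0.05 these lists held 1, 6, 3 and 0 RNAs in the authors' deposited table. Of the 3 genes named as snRNA pseudogenes, 1 passed, RNU2-2P, also when adjusted over the list alone. No row was named TERC, but a telomerase RNA model inside that gene, AC078802.2, had 134 reads. Its genome-templated end differed by −0.847 nt and its total end by −1.23 nt in the authors' deposited table. Neither passed (limma's moderated test, adjusted p of 0.661 and 0.484).

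The second comparison asked whether Sm-class snRNAs stood apart from RNAs that differ from them in cap, ring or polymerase. Of the Sm-class RNAs, 18.2% were called (2 of 11) against 0.781% of the others (1 of 128, RNU2-2P), for the genome-templated and the total end alike (Fisher's exact test, 2-sided, p = 0.0165). With a change of at least 1 nt required, 1 of 11 was called for the genome-templated end (Fisher's exact test, p = 0.153). At an adjusted p under 0.01, 0 of 11 were called for the total end. RNU2-2P is a U2 gene, kept outside the Sm class because its symbol marks it as a pseudogene. With Sm-family pseudogenes counted in the class, 3 of 13 were called against 0 of 126 others (Fisher's exact test, p = 0.000653). The genome-templated and the total end gave the same values there. The median change of the genome-templated end was 0.756 nt in the Sm class, with 9 of 11 RNAs above 0, against −0.212 nt in 67 H/ACA snoRNAs, −0.200 nt in 19 C/D snoRNAs and −0.0972 nt in 14 RNA polymerase III RNAs. Each of these 3 differences passed a permutation test adjusted over 12 comparisons, at 0.968 nt (adjusted p = 0.000360), 0.956 nt (adjusted p = 0.0331) and 0.853 nt (adjusted p = 0.0248). The difference from 16 scaRNAs was 0.903 nt and missed the threshold (permutation test, adjusted p = 0.0706). The differences from U3, U8 and U13 (0.814 nt, exact permutation test, adjusted p = 0.182) and from U6 and U6atac (0.536 nt, exact permutation test, adjusted p = 0.4231) also missed it; with 2 U6-type RNAs the smallest p possible was 0.0128.

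For the total end the Sm-class median was 0.969 nt, and the differences from H/ACA snoRNAs (1.30 nt, adjusted p = 0.00108), RNA polymerase III RNAs (1.26 nt, adjusted p = 0.0107) and C/D snoRNAs (1.14 nt, adjusted p = 0.0386) passed the permutation test. Those from U3, U8 and U13 (1.15 nt), from U6-type RNAs (1.43 nt) and from scaRNAs (0.831 nt) had adjusted permutation p of 0.0742, 0.182 and 0.182. Against random lists matched on read number, the Sm-class median of the genome-templated end lay at percentile 99.91 and that of the total end at percentile 99.8, with adjusted p of 0.0688 for both over 40 class values, so no class passed. The same adjusted p was found for the total end of H/ACA snoRNAs (median −0.329 nt, percentile 0.33) and of 3 vault RNAs (−6.72 nt, percentile 0.22), both medians upstream, and for the Sm-class share of tails of 3 or more A (0.666 percentage points, percentile 99.775). Of the 3 vault RNAs, 1 had its total end further downstream. They are annotated at 89 to 99 nt, below the 100 nt lower cut of the gel, as are some C/D snoRNAs. With means in place of medians the Sm class stood at percentile 77.88 for the genome-templated end and 99.15 for the total end. RNAs are not independent replicates, and these tests describe the RNAs of this table. With 1 RNA per family the genome-templated difference held against H/ACA snoRNAs (exact permutation test, adjusted p = 0.00298) and not against C/D snoRNAs (0.143) or RNA polymerase III RNAs (0.183), and with means in place of medians it was lost in all 3 (adjusted permutation p of 0.0668, 0.132 and 0.385). The total-end difference held with means in all 3 (adjusted permutation p of 0.00012, 0.0042 and 0.0042). With 1 RNA per family it was lost against RNA polymerase III RNAs (exact permutation test, adjusted p = 0.183). With at least 100 reads per condition it was lost against C/D snoRNAs (exact permutation test, adjusted p = 0.0952).

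**Figure D3:**
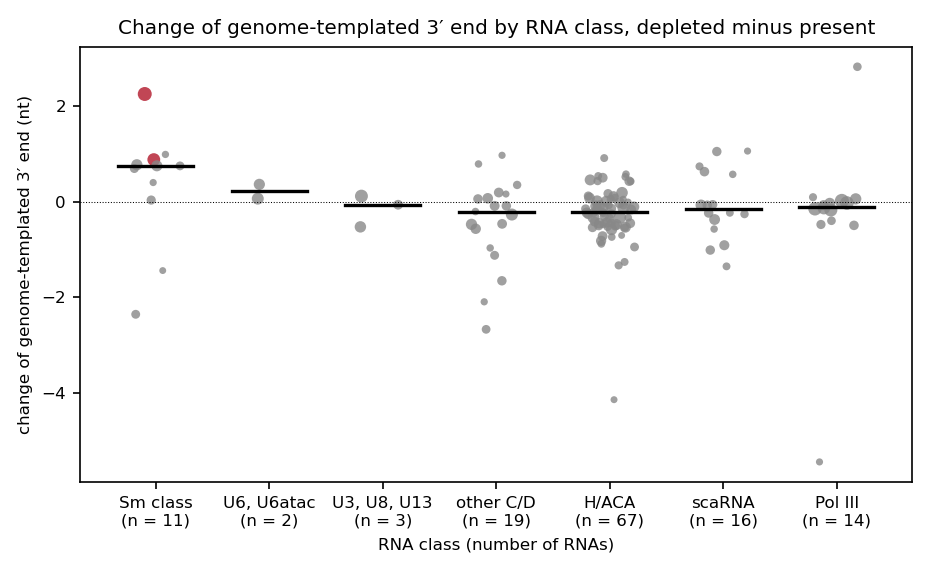
Change of the genome-templated 3′ end, TOE1-depleted minus TOE1-present (nt, y axis), by RNA class (x axis). Each point is 1 RNA, larger with more reads; red marks adjusted p under 0.05 and black lines are class medians. The Sm-class median is 0.756 nt, and the H/ACA median −0.212 nt.

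The third comparison concerned untemplated tails. Reads ending in A were fewer in TOE1-depleted libraries for most RNAs: the share with a tail of 1 or more A was lower for 99 and higher for 29 of 128 RNAs in the authors' deposited table, and 24 lower and 3 higher values had an unadjusted p under 0.05. None passed the adjusted threshold. Over 57 RNAs with at least 200 reads, the median share was 19.2% in TOE1-present and 10.2% in TOE1-depleted cells, lower in 52 and higher in 5. RN7SL1, the RNA of the signal recognition particle, went from 57.0% to 47.3%, U6atac from 44.7% to 17.9% and U13 from 31.3% to 11.3% in the authors' deposited table, each with an adjusted p of 0.214.

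RNU2-2P and U1 had higher shares, and U2, like most RNAs, a lower one; none of these passed, and the difference from other RNAs was not tested. In RNU2-2P the share with 1 or more A was 4.92% with TOE1 and 13.7% without it in the authors' deposited table (95% interval of the difference 6.02 to 11.5 percentage points, adjusted p = 0.113). U1 stood at 17.7% and 24.7% (−5.01 to 19.04 percentage points, adjusted p = 0.350), and U2 at 20.7% and 15.3% in the authors' deposited table (adjusted p = 0.214). Tails of 3 or more A were found on 1.85% and 5.399% of U1 reads and on 0.422% and 1.27% of U2 reads, in TOE1-present and TOE1-depleted cells, in the authors' deposited table, with adjusted p of 0.227 and 0.0922. RNU4-1, with 111 reads, had 2.78% and 23.0% in the authors' deposited table (adjusted p = 0.310). In 13 tail measures, each adjusted over its own RNAs, 3 values passed the threshold, all in H/ACA snoRNAs named after their values were seen. SNORA48 (738 reads) fell from 17.7% to 7.71% in tails of 2 or more A and from 16.8% to 5.10% in tails of 3 or more A in the authors' deposited table, with adjusted p of 0.0435 and 0.0108. In SNORA67 (169 reads) the U bases rose from 0 to 0.142 nt per read in the authors' deposited table (adjusted p = 0.0387). The tail shares have no per-library values, and AG11 was ligated in 2 of the 3 TOE1-depleted libraries, so the wide difference in A tails and the adaptor cannot be told apart by a fit within AG10 libraries.

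**Figure D4:**
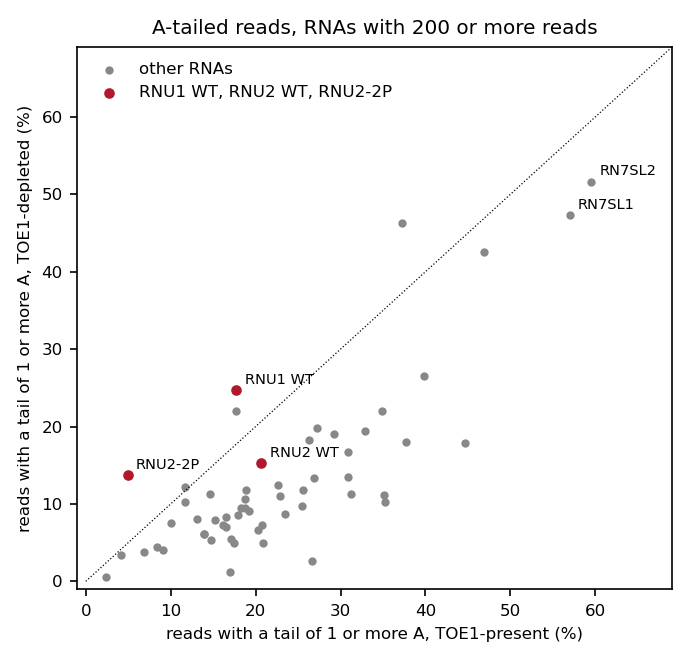
Share of reads with a tail of 1 or more A in TOE1-present cells (%, x axis) and TOE1-depleted cells (%, y axis) in the authors' deposited table, for 57 RNAs with at least 200 reads; each point is 1 RNA and the dotted line marks equal shares. Of these, 52 lie below the line, and RNU1 WT and RNU2-2P lie above it.

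The fourth comparison was of read abundance. Of 101 RNAs tested with edgeR, 5 were higher and 3 lower in TOE1-depleted libraries at an adjusted p under 0.05, all but the control RN7SL1 named after their values were seen. Among the 7SL RNAs, RN7SL1 went from 305558 ± 70803 to 142247 ± 7757 TMM-normalised CPM (mean ± SD, n = 3 per group; log2 change −1.10 ± 0.25 SE, edgeR adjusted p = 0.0445) and RN7SL3 by a log2 change of −1.13 ± 0.23 SE (edgeR adjusted p = 0.0348). The RN7SL2 value was −1.02 ± 0.24 SE with an edgeR adjusted p of 0.0508, and adjusted over the list alone all 3 passed. With the replicate block RN7SL2 passed over all RNAs (edgeR adjusted p = 0.0178), but the pairing behind that block rests on rows of the RMRP and U2 families. RNU2-59P, a U2 pseudogene, was lower by a log2 change of −0.78 ± 0.13 SE (edgeR adjusted p = 0.0348), which was −0.24 and not called (edgeR adjusted p = 0.383) when scaled by library totals alone. The H/ACA snoRNAs SNORA3A, SNORA44 and SNORA70 rose with log2 changes of 0.93, 0.57 and 0.65, the Cajal body RNA SCARNA8 with 1.43 and the C/D snoRNA SNORD83A with 1.22, each with an edgeR adjusted p of 0.0348. For these 8 RNAs the 3 TOE1-depleted libraries lay on 1 side of the 3 TOE1-present libraries, which their being called in part ensures. The same held for 32 of the 101 RNAs, or 31.7%, where chance gives 10% for a single RNA. All RNAs share the same libraries and TMM factors, so setting 31.7% against 10% is not a test. RN7SL1, RN7SL2 and RN7SL3 had negative log2 changes under each alternative run, with RN7SL1 between −1.28 and −0.53, but none was called when scaled by library totals alone, at −0.53, −0.43 and −0.55 (edgeR adjusted p of 0.207, 0.345 and 0.124).

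U1, U2 and RNU2-2P did not pass in abundance, with log2 changes of −0.03 ± 0.19, −0.50 ± 0.22 and −0.33 ± 0.20 SE and edgeR adjusted p of 0.952, 0.197 and 0.364; scaled by library totals alone, which raised the median of all RNAs by 0.55 on the log2 scale, these read 0.53, 0.06 and 0.24. DESeq2, run with its own test, called the row RNU2 WT lower (adjusted p = 0.00887), but that row leaves out the reads on AC024051.4. With the models summed, a test added after the data were seen, edgeR gave U2 a log2 change of −0.19 ± 0.43 SE (adjusted p = 0.882), and as a share of the library the sum was 26.4%, 20.9% and 14.5% in TOE1-present and 33.1%, 21.9% and 19.3% in TOE1-depleted replicates 1 to 3. The controls RN7SK and RPPH1 had log2 changes of −0.67 ± 0.17 and −1.22 ± 0.52 SE (edgeR adjusted p of 0.0508 and 0.196), and RNVU1-31 and U13 of −0.77 ± 0.20 and 0.56 ± 0.17 SE (0.0508 and 0.0924). These 4 passed with the replicate block, at −0.68, −1.43, −0.76 and 0.58 (edgeR adjusted p of 0.0150, 0.0273, 0.0119 and 0.0340), while 7SK with its models summed stood at 0.03 ± 1.40 SE. The replicate numbers were taken as pairs because of the RMRP and U2 rows only. The RPPH1 value was unstable, at −1.81 without TOE1-depleted replicate 1, −0.82 without TOE1-depleted replicate 3, −0.51 in AG10 libraries alone and −0.48 with the adaptor as a covariate. U3 (row SNORD3) had a log2 change of −0.72 ± 0.21 SE (edgeR adjusted p = 0.0924). Adjusted over their list alone, U13 passed as higher and U3 as lower. Over each list alone, the C/D and scaRNA lists held 1 higher and 1 lower RNA each, and the 7SK and vault RNA lists 1 lower each. The H/ACA list held 3 higher, and the Sm class 0. The counts over all RNAs moved with the settings: 8 higher and 10 lower with the replicate block, 4 and 8 with DESeq2 size factors, and 31 and 0 with library totals in place of TMM. No single library could be left out with the count kept: edgeR gave 0 higher and 0 lower without TOE1-present replicate 1, TOE1-present replicate 3 or TOE1-depleted replicate 3 (22, 22 and 27 RNAs at an unadjusted p under 0.05), 0 and 1 without TOE1-present replicate 2, 1 and 1 without TOE1-depleted replicate 1, and 1 and 0 without TOE1-depleted replicate 2. The log2 changes themselves kept their direction, with SCARNA8 between 1.24 and 1.55, SNORA3A between 0.76 and 1.02, RNU2-59P between −0.89 and −0.73 and RN7SL1 between −1.28 and −0.94 over the libraries left out. The 4 AG10 libraries hold 1 TOE1-depleted library, assumed to vary like the others, so the 0 calls of edgeR there (19 at an unadjusted p under 0.05) say little; the 5 higher RNAs had log2 changes of 0.51 to 1.68 and the 3 lower ones of −1.22 to −0.63.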

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

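All tests in this part were chosen after the results were seen.

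Reads on gene models outside the end comparisons stood out in replicate 1 of both groups. AC024051.4, a U2 model, held 21.0% of the reads of TOE1-depleted replicate 1 and 9.81% of those of TOE1-present replicate 1, and AL162581.1, a 7SK model, held 8.42% and 6.19%.

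If the reads of a family were only divided between its models in another way, the family sum would stay the same. Against this for 7SK, the sum was 16.54 times as large in TOE1-depleted replicate 1 as in the mean of replicates 2 and 3, and 11.96 times in the TOE1-present group. RN7SK lies within AL162581.1 on the same strand, and how reads that match both were counted is not given. The sums therefore do not show how much 7SK RNA a library held. For RMRP the larger difference of the 2 groups was 1.59-fold and for U2 1.604-fold, and the explanation stays open for both. The bound of 1.5, a measure per 100 reads outside the 3 families (1.19-fold for RMRP, 2.14-fold for U2) and the demand that both measures pass it in both groups were each set after values were seen, the second after RMRP had passed the bound on the first and the third after U2 had passed it on both. Replicate 1 stood apart in both groups, so the pattern did not follow TOE1, and no biological explanation was tested.

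The downstream ends of U1, U2 and RNU2-2P were weighed against 3 technical explanations. Against the adaptor AG11 as the whole cause, the smallest statistic of the 3 RNAs was 12.78, which the choice of called RNAs in part ensures, and the deposited differences and p place TOE1-depleted replicate 1, ligated with AG10, at least 0.749 nt (U1), 2.05 nt (U2) and 6.43 nt (RNU2-2P) downstream of the TOE1-present mean. For U2 this covers the row RNU2 WT, with 9098 reads in that library. The 15817 reads on AC024051.4 there have no end values, and how the division between the 2 rows affects the U2 bound was not tested. A shift of all ends is argued against by the other 136 RNAs, whose median change was −0.1151 nt, with quartiles of −0.469 and 0.124 nt, below the 0.888 nt of U1. Still open is a change in which of several near-identical gene copies the reads come from, since 2 of the 3 rows merge genes and no values per copy were available. The loss of TOE1, the difference the design names, also stays open; RNU2-2P is the row of the 3 that holds a single gene.

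The lower share of reads with an A tail in TOE1-depleted libraries may come from the adaptor, but the test does not decide it. Without noise between libraries, a pure shift in the 2 AG11 libraries gives a statistic of 2, and noise scatters the values to both sides. Over 57 RNAs with at least 200 reads the median was 1.993, 28 lay over 2 and the upper quartile was 2.88. Values over 2 therefore do not count against the adaptor. The median alone was first read as favouring the adaptor, and the upper quartile was added to the test afterwards. An equal effect of TOE1 loss in 3 noisy libraries can give such values too, and 0 RNAs passed the adjusted threshold, with 17 of the 57 at an unadjusted p under 0.05. The adaptor and TOE1 loss cannot be told apart here, because no tail shares per library were available.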

How the results depend on the processing

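The tests named here as added were chosen after the data were seen: limma's moderated test, the Kolmogorov-Smirnov p, the DESeq2 Wald test, library totals, the fits without 4 rows or with their models summed, the adaptor covariate and the splits of the libraries. End positions and tails have no values per library, so the replicate block, leaving out a library, AG10 libraries alone and other normalizations were run for counts only; the pseudocount alternative was for deposited normalized values, of which there were none. Of 432 alternative values, 286 kept their direction and side of the threshold, or for counts stayed within 1.5 times. The same 3 downstream ends were called under each alternative for the genome-templated end except the minimum of 1 nt, which left 2. For the total end an adjusted p under 0.01 left 0 (11 at an unadjusted p under 0.05, and 3 by limma at 0.05) and Bonferroni 2, without U1. An adjusted p under 0.1 added 1 upstream genome-templated end. The added Kolmogorov-Smirnov p called 6 downstream and 6 upstream genome-templated ends and 6 downstream and 16 upstream total ends; it counts reads as replicates. The excess of called Sm-class RNAs was 8.31 percentage points with 1 nt required (Fisher's exact test, p = 0.153) and 0 for the total end at an adjusted p under 0.01. The Sm class minus C/D snoRNAs, called before, was not called with at least 100 reads per condition (1.10 nt, and 1.30 nt for the total end). There 4 Sm-class RNAs and 5 C/D snoRNAs were tested. With means, the genome-templated differences from C/D (0.765 nt), H/ACA (0.596 nt) and RNA polymerase III RNAs (0.655 nt) were not called; the Sm-class mean was 0.345 nt against a median of 0.756 nt. With 1 RNA per family those from C/D (0.958 nt) and RNA polymerase III RNAs (0.901 nt, and 1.47 nt for the total end) were not called. That setting tests fewer RNAs and also removes related copies, which cannot be told apart. With pseudogenes counted in the Sm class that from scaRNAs was called (0.903 nt). Abundance counts, 5 higher and 3 lower with edgeR, moved in 35 of 42 values. They were 8 and 10 with the replicate block, 0 and 0 at an adjusted p under 0.01 or with Bonferroni (28 at an unadjusted p under 0.05), and 7 and 10 at 0.1. They were 2 and 2 with 1 log2 unit required, 3 and 2 with no filter, 4 and 8 with DESeq2 size factors, 0 and 0 in AG10 libraries alone (19 unadjusted), where the TOE1-depleted arm is 1 library and the folds of the 8 RNAs kept their direction, and 2 and 0 with at least 100 reads, where the median shifted by 0.16. Of the added ones, the adaptor covariate gave 0 and 0 (20 unadjusted) with the 8 folds in the same direction and larger errors, the DESeq2 Wald test 5 and 13, library totals 31 and 0, and the fit without the 4 rows 6 and 12, or 9 and 12 with the block. With the models of 3 families summed they were 5 and 8. Leaving out each library gave 0 to 1 higher and 0 to 1 lower. U1 abundance, not called in any of these, reversed to 0.0197 without TOE1-depleted replicate 1, ranging from −0.114 to 0.0197 over the libraries left out, to 0.110 with at least 100 reads and to 0.533 with library totals, and U2 and RNU2-2P reversed to 0.0617 and 0.241 with library totals. The cause of these moves was not tested. TMM factors were 0.764 to 0.932 in TOE1-present and 0.992 to 1.41 in TOE1-depleted libraries, and the counts cannot tell which scaling is right. Of the 10 splits of the 6 libraries, 1, the real one, gave 8 calls and the highest other 0; 10 splits are too few for a share under 0.05. What depth limits was not tested by varying it: the median RNA had 170.5 reads, libraries of a group differed by at least 14.5 times sampling noise in chi-square per degree of freedom, and the simulated main test recovered 1.5% of 1.5-fold and 33.5% of 2-fold changes.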

Other observations

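The test of A tails against end changes was chosen after the results were seen; the test of control end positions was written before. Whether RNAs that end further downstream in TOE1-present cells shift further on depletion was tested across 59 RNAs with at least 200 reads, which are not independent replicates. Spearman's rho was −0.1544 (permutation p = 0.244, adjusted over 2 relations 0.244) and Pearson's r −0.0674 (permutation p = 0.570), so the relation was not found. The control position enters both measures, and its noise pulls the correlation below 0. Whether RNAs whose ends move downstream gain tails of 3 or more A stayed undecided, with a rho of 0.2095 (permutation p = 0.112, adjusted 0.225) and an r of 0.105 (permutation p = 0.211). Without the 3 called RNAs rho was 0.106, and without the Sm-class families it was 0.000288 over 53 RNAs.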
